A study of Mus musculus with 6 samples.

How the data were processed

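RNA was measured in granulocyte-macrophage progenitors (GMPs), bone marrow cells committed to making granulocytes and monocytes, that were sorted from C57BL/6 mice. Per the labels, the sort took Lineage-negative, c-Kit-positive, Sca1-negative, CD34-positive cells stained for Fcγ receptors. The 6 libraries fell into 2 groups of 3: Bap1 f/f mice without Cre (control) and Mx1-Cre Bap1 f/f mice (Bap1 knockout), in which polyI:polyC induces Cre through the interferon-responsive Mx1 promoter. Per the labels, the mice were 65 days old and had received polyI:polyC at 42 days, while the design text of the series places the injections earlier in life; the labels' ages are used here. Per the labels' protocols, total RNA was amplified with a SMARTer low-input kit and made into whole-transcriptome Ion Torrent libraries, so reads came from PCR without molecular identifiers. Floors drawn from 3 reads therefore cover counting error only, while SDs and SEs cover the spread between libraries.

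The submitters' processing notes name Picard, STAR, BWA 0.7.5a, HTSeq and DESeq2 and the mm9 and NCBIM37 mouse builds, without saying what each was used for. Whether counting used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited values, a signal per gene and library, were gene counts that the authors had divided by 1 size factor per library: in each library 100% of the values above 0 were whole multiples of its smallest step, within a tolerance of 0.01 of a read. That step, the value of 1 read, ran from 0.8885 to 1.1419, and dividing by it gave back the whole reads of 37620 gene rows and 5 rows that name no gene. Gene reads came to 19.5 to 25.9 M per library, 22.9 to 25.2% of all reads listed. Of all reads listed, 38.39 to 40.9% lay outside genes, 26.76 to 28.79% aligned to several places, 6.3 to 11.62% did not align, and 0.12 to 0.13% were ambiguous. These rows were kept out of library sizes and tests. Reads that align to several places were not assigned to genes, so genes with close copies or processed pseudogenes are undercounted: Gapdh stood at 94.3 ± 19.18 normalized counts in control libraries (SD, n = 3). Of the 37620 gene IDs, 32897 had a symbol in the GENCODE M21 annotation, as did 93.7% of the 20738 genes with a read. That annotation is on another build (GRCm38) than the authors' files, so it was used for names, transcript lengths and GC content, and no coordinates are given.

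A test on counts had been planned before the data were examined, and the deposited values turned out to be scaled. The main test was therefore limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(deposited value + 1), over genes with a mean deposited value of at least 10, with group as the sole term, 2-sided, at a Benjamini-Hochberg adjusted p of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The planned edgeR 4.0.16 quasi-likelihood test on the recovered reads was run as an added alternative: it tested 14458 genes and called 1687 higher and 2077 lower, of which 3663 were called in the same direction by limma. The limma steps were tested on simulated counts for 14293 genes with the libraries' own means, depths and spread. Each gene had 1 spread shared by both groups, as in the limma fit, although the knockout-labelled libraries differed more among themselves. In these counts, 48 to 50 tested genes were set to change by each known fold. They called 16.7% of genes changed 1.5-fold, 60% of those changed 2-fold, 89.6% of those changed 4-fold and 95.8% of those changed 8-fold. Of the 138 simulated calls, 11 were false (8%) and 0 had the wrong sign. Far fewer genes changed there than the 26.8% called in the data. The adjusted p threshold was thus stricter in the simulation, and these shares can understate what is called here.

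A set of 34 gene lists was fixed before the data were examined. The 31 with at least 5 tested members, sex-linked genes aside, were tested with limma's camera, a competitive test of whether a list's genes move more than other genes, 2-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 31 lists. It was planned on voom-weighted counts and run on the log2 values above. With an estimated correlation, 0 of the 31 lists passed in either direction, and that adjusted p is given beside each call. limma's fry, which asks whether a list's own genes move one way without comparing them to other genes, called 0 lists higher and 10 lower. Members are counted as having risen or fallen by the limma adjusted p over all genes, and also adjusted over the list alone. In 6 lists (stem and multipotent, B lymphoid, T and NK, stromal, interferon and immediate-early) 1 or 2 members had 0 reads in a whole group; with these set at the bound that 3 reads per library allow, the list medians stayed at the values given.

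The genes named in the text followed a rule set at the same time. It took Bap1, every called member of the BAP1 partner, PRC2 and HOXA lists, and Ezh2, L3mbtl2, Hoxa9 and Meis1 whatever their result. It also took the 12 called genes with the largest change in each direction that separated all libraries of the groups, had an average log2 CPM of at least 3 and were not predicted models, and up to 3 members of each list with the smallest p, of which a few are not given in the text. Genes outside the rule are said to be chosen after their values were seen, and the genes of the sort gate are given as checks. Folds against a group with 0 reads in every library are lower bounds computed from 3 reads per library. The alternatives planned were edgeR with other size factors, robust fitting or a minimum fold, DESeq2 1.42.0, voom with quality weights, other filters and thresholds, the replicate number as a block, and leaving out each library. Added after seeing the data were other pseudocounts, a higher mean filter, TMM scaling within limma, sex as a term, and a correction for GC content and transcript length. Replicates are separate samples per the labels, and nothing states that each came from its own animal, so p-values measure the spread between these samples.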

Results

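GMP transcriptomes were compared between 3 libraries labelled control (Bap1 f/f, no Cre) and 3 libraries labelled Bap1 knockout (Mx1-Cre Bap1 f/f), to find which genes change when Bap1, a nuclear deubiquitinase that acts on histone H2A, is deleted. Mx1-Cre was carried only by the knockout-labelled group, so an effect of Cre cannot be told apart from one of Bap1 deletion. The title of the series places the effect of Bap1 loss in relation to EZH2, the methyltransferase of Polycomb repressive complex 2 (PRC2). Control libraries held 24.1 to 25.9 M gene reads and knockout-labelled libraries 19.5 to 24.1 M, with reads in 17090 to 17509 genes. Log2 values correlated at r = 0.961 to 0.974 between libraries of a group and 0.898 to 0.918 between groups, across genes, which are not independent replicates. The main principal component, with 61.6% of the variance, separated the groups. All 6 pairs of replicates differed far beyond counting noise, so each library was counted separately. The chi-square per gene was 13.3 to 17.9 between control libraries and 42.4 to 51.2 between knockout-labelled libraries. These values do not show that each library came from its own animal. Xist and Y-linked genes showed that control replicate 1 and knockout replicate 3 came from female mice and the others from male mice, so each group held 1 female.

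Bap1 (ENSMUSG00000021901) was higher, not lower, in the libraries labelled Bap1 knockout. Its normalized count was 1343, 998.5 and 1076 in the control libraries and 2671, 3309 and 2968 in the knockout-labelled libraries, or 1139 ± 181 against 2983 ± 319.1 (SD, n = 3 each), a 2.63-fold difference (log2 fold change 1.39, SE 0.14, limma adjusted p = 6.07e-05). This goes against the labels. A count over the whole gene includes any exons outside the deleted part, so it does not check the deletion, and every direction below is that of the libraries labelled knockout.

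Ezh2 itself did not change detectably, with 2752 ± 85.21 normalized counts in control and 2611 ± 292.9 in knockout-labelled libraries (SD, n = 3; log2 fold change -0.08, SE 0.12, limma adjusted p = 0.659). Of 11 tested PRC2 genes, 0 rose and 1 fell: Mtf2, a Polycomb-like accessory subunit, with a log2 fold change of -0.64 (SE 0.13, limma adjusted p = 0.00391). Adjusted over the list alone, that count was also 0 and 1. Ezh1, the other methyltransferase of PRC2, was at 292.5 ± 31.39 and 415.5 ± 76.13 (adjusted p = 0.0813), and Eed at 2005 ± 214.5 and 1632 ± 220.7 (0.133); without knockout replicate 1 both passed (0.0422 and 0.0459), as did Ezh1 after GC and length correction (0.0186). L3mbtl2, a member of a variant PRC1 complex and a reader of repressed chromatin, was at 1177 ± 150 in control and 1306 ± 271 in knockout-labelled libraries (limma adjusted p = 0.575). Among 12 BAP1 partner genes, 0 rose and Hat1, a histone acetyltransferase, fell by 0.43 on the log2 scale (limma adjusted p = 0.0392); adjusted over the list alone, 0 passed. The Hat1 call was lost without control replicate 1 (adjusted p = 0.0625), 2 (0.124) or 3 (0.156), without knockout replicate 2 (0.0543) or 3 (0.0772), without a filter beyond 1 read (0.0578), and after GC and length correction (0.326). The BAP1 partners Asxl2 (985.2 ± 2.493 and 786.8 ± 101.6, adjusted p = 0.106, but 0.0343 without knockout replicate 1) and Foxk1 (84.9 ± 19.78 and 133.9 ± 44.39, 0.17) did not pass. Of 23 PRC1 genes, 2 rose and 4 fell (3 and 4 adjusted over the list alone). The lowest p belonged to Rnf2, the catalytic RING1B subunit, at 2258 ± 143.4 against 1454 ± 240.3 normalized counts (limma adjusted p = 0.00579, but 0.051 after GC and length correction). The chromobox gene Cbx7 rose 2.94-fold (adjusted p = 0.0184; 0.0637 without control replicate 2 and 0.0717 without knockout replicate 3). Cbx6 was 2.02-fold lower (0.0206), and its call was lost without control replicate 1 (0.075) or 2 (0.0774) and without knockout replicate 1 (0.0559) or 2 (0.0649). Camera called none of the PRC2 (adjusted p = 0.338), PRC1 (0.571) and BAP1 partner (0.576) lists, and the PRC2 median turned from -0.22 to 0.02 after GC and length correction.

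**Figure D1:**
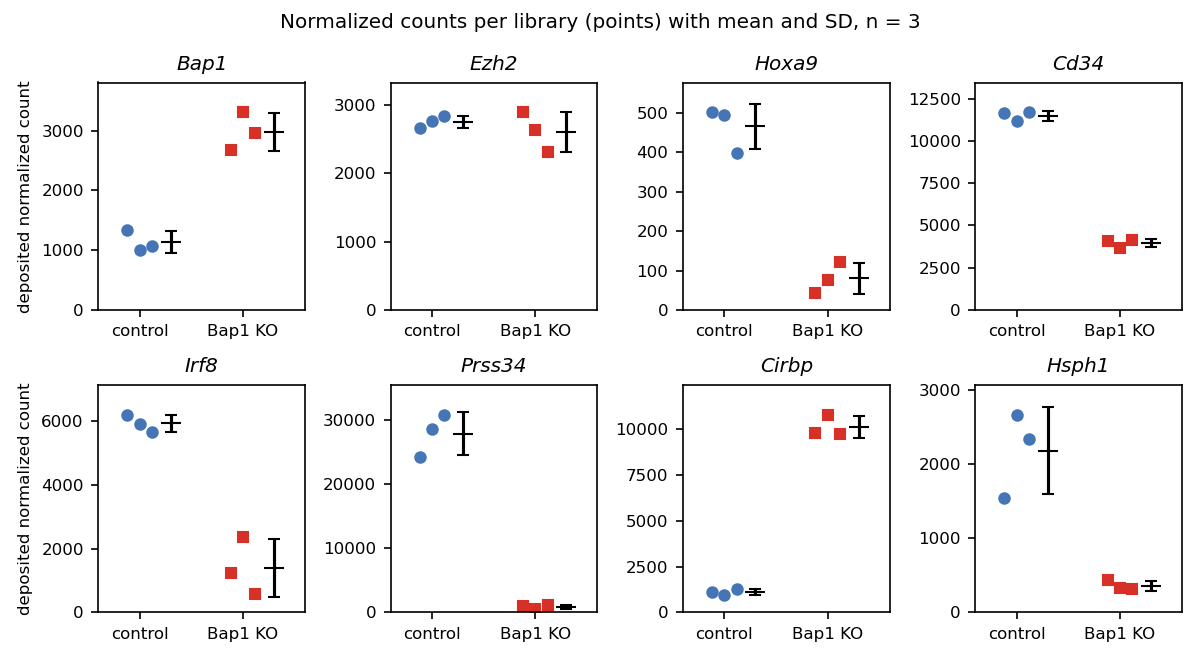
Normalized count per library (points, y axis from 0) for 8 genes in 3 control and 3 knockout-labelled libraries, with the mean and SD of each group beside the points. Bap1 was higher in all knockout-labelled libraries (2671 to 3309) than in any control library (998.5 to 1343), Ezh2 overlapped between the groups, and Hoxa9, Cd34, Irf8, Prss34 and Hsph1 were lower while Cirbp was higher.

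In all, 1695 genes were higher and 2163 lower in the libraries labelled knockout, 26.8% of the 14391 genes tested by limma. At least 2-fold changes were seen in 673 and 1183 of them, and at least 8-fold changes in 132 and 274. The largest rise was that of Tcp11x2, an X-linked member of a testis-expressed family, with 0 reads in every control library and 1128 ± 280.8 normalized counts in the knockout-labelled libraries, at least 412-fold higher. Tcf7, the T-lineage transcription factor TCF1, went from 42.24 ± 14.09 to 457.3 ± 94.24 (10.8-fold), and Cirbp, a cold-inducible RNA-binding protein, from 1109 ± 163.8 to 10130 ± 589.7 (9.18-fold). Perp, a p53 target of cell adhesion, rose 10.7-fold, Dcbld1 47.1-fold, Cnmd (chondromodulin) 23.2-fold, Smim6 15.5-fold, the collagen gene Col5a1 10.8-fold, Cyb561 10.6-fold, Prrg4 9.80-fold and the C-type lectin Clec4b2 9.15-fold. Tcrg-C1, a T cell receptor gamma constant gene with close copies and therefore an uncertain count, was at 0.637 ± 1.103 in control and 427.5 ± 269.7 in knockout-labelled libraries. Among the genes that fell, Prss34, a basophil and mast cell protease, went from 27880 ± 3337 to 891 ± 294.5, 32.4-fold lower. Cx3cr1, the fractalkine receptor of monocytes, was 25.8-fold lower, Stat4, which transmits interleukin-12 signals, 22.1-fold, the heparanase gene Hpse 18.7-fold, the beta-glucan receptor Clec7a 16.4-fold and Tfpi, an inhibitor of coagulation, 16.0-fold. Nrp1 (log2 fold change -4.99), Pkib (-4.70), Dnajc12 (-4.50), Gng2 (-4.36), B4gat1 (-4.15) and Lpxn (-3.96) completed the 12 largest falls, with limma adjusted p values of 7.22e-05 or less. Without knockout replicate 3, Nrp1 was at -4.29 and Pkib at -3.95. The counts of genes dropped to 1032 higher and 1417 lower without control replicate 2 and to 1053 and 1372 without control replicate 3, and a correction for GC content and transcript length turned the split to 2710 higher and 1966 lower, so that 42% of calls were lower in place of 56.1%.

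**Figure D2:**
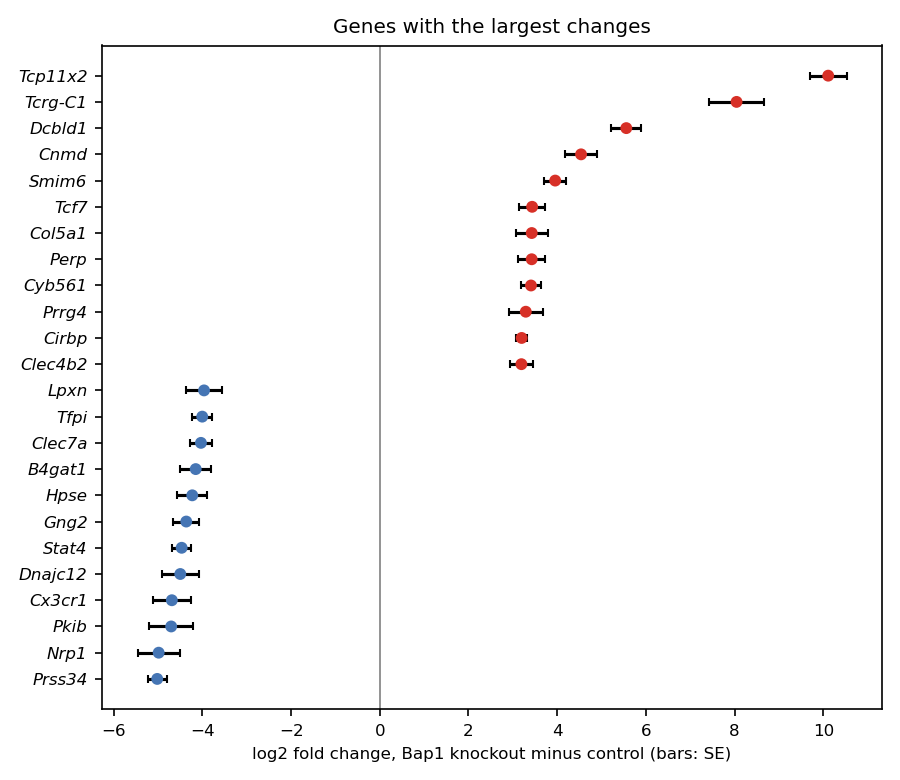
Log2 fold change (x axis, knockout-labelled minus control libraries, n = 3 each) of the 12 genes with the largest rise and the 12 with the largest fall under the rule, with bars of 1 SE from limma. Prss34 had the lowest value (-5.02), and the values of Tcp11x2 and Tcrg-C1, with 0 or few reads in control libraries, depend on the pseudocount.

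Hoxa9, a homeobox gene of stem and progenitor cells, fell from 465.7 ± 57.6 to 80.26 ± 38.83 normalized counts (SD, n = 3), 6.20-fold, with a log2 fold change of -2.63 (SE 0.33, limma adjusted p = 0.000199). Hoxa7 fell with it (-2.23, SE 0.42, adjusted p = 0.00265), while Meis1, a cofactor of HOXA9, was at 704.7 ± 53.49 and 694.9 ± 286.9 (adjusted p = 0.793). These were the only called members among 7 tested HOXA, MEIS and PBX genes, also adjusted over the list alone, and Pbx3 was at 37.45 ± 16.74 against 15.29 ± 6.064 (adjusted p = 0.118). The list, with a median log2 fold change of -1.23, did not pass camera (adjusted p = 0.115); it passed in edgeR on the recovered reads (0.0385) and without knockout replicate 3 (0.0306), and its median was -0.36 without knockout replicate 1. Over genes with a mean value of at least 50, the median was -0.13 (adjusted p = 0.244).

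Stem cell and GMP genes split in both directions. Among 27 stem and multipotent progenitor genes 3 rose and 5 fell, also adjusted over the list alone (median -0.13, camera adjusted p = 0.465). Procr, the endothelial protein C receptor of stem cells, had 0 reads in the knockout-labelled libraries against 22.49 ± 3.308 normalized counts in control, at least 6.92-fold lower. Among 25 GMP and myeloid transcription factor and receptor genes 5 rose and 6 fell (6 and 6 adjusted over the list alone). Irf8, which directs progenitors to monocytes and dendritic cells, fell from 5933 ± 266 to 1396 ± 897.6 (4.95-fold, limma adjusted p = 0.000833), and Csf1r, the macrophage colony-stimulating factor receptor, 5.39-fold. This list had a median of 0.22, a mean of -0.15 and a camera adjusted p of 0.648, upwards. Of the genes of the sort gate, Cd34 fell from 11500 ± 296.5 to 3963 ± 243.6 (log2 fold change -1.54, SE 0.11, adjusted p = 5.04e-06) and Fcgr3 by 0.77 on the log2 scale (adjusted p = 0.00198). Fcgr2b was at 2665 ± 194.7 and 2392 ± 86.92 (adjusted p = 0.346). Kit was 1.39-fold higher (adjusted p = 0.0214), a call lost without control replicate 1 (0.0783), control replicate 3 (0.0936) or knockout replicate 3 (0.054).

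Of the lists of mature myeloid cells, camera called secondary granule genes higher, and monocyte, dendritic, and mast cell, basophil and eosinophil genes lower, in the libraries labelled knockout. Of 27 secondary granule and neutrophil maturation genes 10 rose and 0 fell (10 and 2 adjusted over the list alone), with a median log2 fold change of 0.70 (camera adjusted p = 0.000285; adjusted p = 0.655 with an estimated correlation, and 0.201 in fry); the median was 0.42 without knockout replicate 2. Pglyrp1, a peptidoglycan recognition protein of granules, rose from 7398 ± 376.9 to 21280 ± 5001, the acute-phase gene Orm1 rose 7.55-fold and the leukotriene B4 receptor gene Ltb4r1 2.40-fold. Of 19 primary granule genes 8 rose and 4 fell (9 and 4 adjusted over the list alone). The fallen ones included Prss34, the protease-activating cathepsin gene Ctsc (5223 ± 253.8 to 1934 ± 329.1, 2.73-fold) and Lyz1, whose reads can be shared with Lyz2 and are uncertain. Mpo, the myeloperoxidase gene, chosen after its values were seen, was at 509900 ± 18680 and 635300 ± 122900 (limma adjusted p = 0.251, but 0.0469 without knockout replicate 1). Also chosen after their values were seen, Serpinb1a, Ms4a3 and Elane were higher by 1.03, 0.76 and 0.69 on the log2 scale (limma adjusted p = 0.00108, 0.00214 and 0.0263). The Elane call was lost without any 1 control replicate (0.09 to 0.123). Prtn3 did not pass (0.467), and Prg2 was lower by 0.54 on the log2 scale (0.00655). The primary granule list had a median of 0.44, a mean of -0.16 and a camera adjusted p of 0.208, upwards, which became 0.00552 without knockout replicate 3.

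Of 30 monocyte and macrophage genes 1 rose and 19 fell (1 and 20 adjusted over the list alone), with a median log2 fold change of -1.58 (camera adjusted p = 1.04e-06; adjusted p = 0.532 with an estimated correlation). F13a1, coagulation factor XIII of monocytes, went from 12570 ± 808.3 to 2187 ± 90.02 (5.74-fold lower, limma adjusted p = 1.47e-07), and Ctss, a lysosomal protease of antigen-presenting cells, was 10.9-fold lower. Among 22 dendritic cell genes 1 rose and 16 fell (2 and 20 adjusted over the list alone; median -2.58, camera adjusted p = 9.73e-07; adjusted p = 0.46 with an estimated correlation). H2-DMa, which loads peptides on class II molecules, went from 4136 ± 223.6 to 547.5 ± 74.92 (7.58-fold lower), Tcf4, a regulator of plasmacytoid dendritic cells, was 7.49-fold lower and Bst2, an interferon-inducible surface marker of the same cells, 4.11-fold lower. Among 23 mast cell, basophil and eosinophil genes 3 rose and 12 fell (4 and 13 adjusted over the list alone; median -1.34, camera adjusted p = 0.000221; adjusted p = 0.46 with an estimated correlation). Beside Prss34, the eosinophil peroxidase gene Epx went from 4814 ± 1059 to 685.3 ± 263.8 and the high-affinity IgE receptor subunit Ms4a2 from 2958 ± 435.3 to 615.5 ± 168.1. Against the list, and chosen after their values were seen, Siglecf of eosinophils rose 1.63-fold, Kit 1.39-fold and the basophil protease gene Mcpt8 from 7027 ± 1139 to 10910 ± 2388 (limma adjusted p = 0.0168). The Mcpt8 call was lost without control replicate 1 (0.0715) or 2 (0.0711), and that of Kit without control replicate 1 (0.0783) or 3 (0.0936) or knockout replicate 3 (0.054). The median of this list was -0.58 without control replicate 3 and -0.48 without knockout replicate 2, -0.54 over genes with a mean CPM of at least 5 and 10 reads in 3 libraries, -0.56 at a mean value of at least 50, and -0.82 with a pseudocount of 4. The gate gene Cd34 moved the same way, 2.91-fold lower in the same libraries.

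Lymphoid genes, which a GMP gate should largely exclude, were read in control libraries, and most of those tested were lower in the libraries labelled knockout. Control means of the B lymphoid genes ran from 21.22 (Bst1) to 10280 (Xbp1). Among 21 tested B lymphoid genes 2 rose and 16 fell (2 and 18 adjusted over the list alone), with a median log2 fold change of -2.91 (camera adjusted p = 1.64e-07; adjusted p = 0.204 with an estimated correlation). Cd79a, a signalling chain of the B cell receptor, went from 163.1 ± 10.48 to 6.922 ± 2.53 normalized counts (21.5-fold lower, limma adjusted p = 3.60e-05). Vpreb3, a pre-B cell gene, was at least 20.0-fold lower with 0 reads in the knockout-labelled libraries. The 2 that rose, chosen after their values were seen, were Sdc1 (46.22 ± 8.698 to 240.6 ± 66.71, 5.03-fold) and Xbp1 (1.33-fold). Among 18 T and NK cell genes 3 rose and 11 fell, or 3 and 13 adjusted over the list alone (median -2.43, camera adjusted p = 0.00173; adjusted p = 0.204 with an estimated correlation). Ncr1, an NK cell receptor, was at 93.68 ± 52.9 and 0.3471 ± 0.6011, and the granzyme gene Gzmb fell 5.50-fold, against the rise of Tcf7. With only genes at a mean CPM of 5 or more and 10 reads in 3 libraries, the camera calls were lost for the B lymphoid (median -0.86, adjusted p = 0.205) and the T and NK lists (0.762), and at a mean value of at least 50 the T and NK call was lost (0.476) and the B lymphoid median was -1.23.

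Camera did not call the erythroid, megakaryocyte and stromal lists, whose members moved in both directions. Of 27 erythroid genes 6 rose and 4 fell (7 and 4 adjusted over the list alone; median 0.33, camera adjusted p = 0.297), with Rhag, a red cell membrane gene, up from 248.7 ± 83.07 to 1273 ± 760.5 and Epor, the erythropoietin receptor, up 4.05-fold, while the carbonic anhydrase gene Car2 was 2.65-fold lower. Of 26 megakaryocyte genes 4 rose and 10 fell (6 and 13 adjusted over the list alone; camera adjusted p = 0.299). Pf4, platelet factor 4, went from 1686 ± 540.8 to 207.5 ± 14.36 and Rab27b was 4.84-fold lower, but Serpine2, a protease inhibitor, rose 2.05-fold. Among 10 stromal and endothelial genes 2 rose and 4 fell (3 and 4 adjusted over the list alone). The adhesion molecule gene Vcam1 rose from 3648 ± 113.4 to 18330 ± 3009 (4.98-fold, limma adjusted p = 1.56e-06), osteopontin (Spp1) fell by 4.63 on the log2 scale and Emcn (endomucin) was at least 11.8-fold lower with 0 reads in knockout-labelled libraries. Without knockout replicate 1 Spp1 was at -5.49 and without knockout replicate 3 at -3.93. That list's median was 0.01 and its mean -1.09, with a camera adjusted p of 0.908, downwards, while fry called it lower (adjusted p = 0.00978), and without a filter beyond 1 read the median was -1.10.

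Interferon-stimulated genes were lower in the libraries labelled knockout. Of 40 tested genes 1 rose and 32 fell, or 2 and 35 adjusted over the list alone, with a median log2 fold change of -1.93 (camera adjusted p = 4.34e-15; adjusted p = 0.204 with an estimated correlation). Ifih1, a sensor of double-stranded RNA, went from 428.9 ± 20.09 to 76.31 ± 10.33 normalized counts (5.59-fold lower, limma adjusted p = 2.07e-05), Ifi203 was 5.78-fold lower and Irf9, a subunit of the interferon-activated transcription complex, 3.17-fold lower. Dendritic and monocyte genes, some of which respond to interferon, were lower in the same libraries, with the medians of -2.58 and -1.58 given above.

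**Figure D3:**
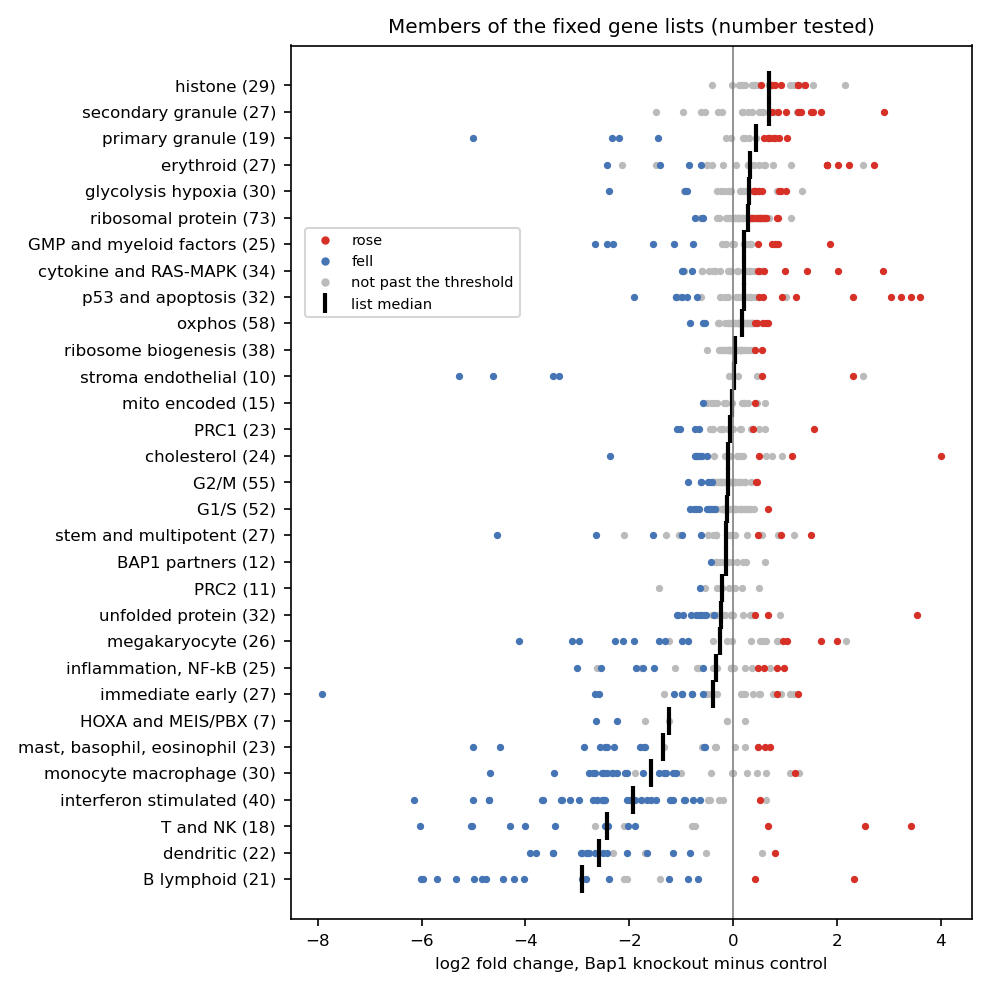
Log2 fold change (x axis, knockout-labelled minus control libraries) of each tested member of the 31 lists tested, with risen (red), fallen (blue) and uncalled (grey) genes by limma and a black bar at the list median; the number tested stands beside each name. Medians ran from -2.91 for B lymphoid genes to 0.70 for histone and secondary granule genes.

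Stress genes moved in both directions. Of 27 immediate-early and dissociation-stress genes 2 rose and 9 fell (3 and 11 adjusted over the list alone; median -0.39, camera adjusted p = 0.195, but 0.0349 after GC and length correction; fry called it lower, adjusted p = 0.0448). The heat-shock chaperone gene Hsph1 went from 2185 ± 582.6 to 357.7 ± 63.73 (6.00-fold lower, limma adjusted p = 1.08e-05) and the antiproliferative gene Btg2 was 1.97-fold lower. Hspa1a, whose reads can be shared with Hspa1b, was at 96.85, 741.5 and 197 in the control libraries with 0 reads in knockout-labelled libraries, at least 106-fold lower, and its fitted log2 fold change of -7.93 became -8.58 without control replicate 1 and -7.12 without control replicate 2. Of 32 unfolded protein response genes 3 rose and 10 fell (4 and 11 adjusted over the list alone; camera adjusted p = 0.0622). Pdia4, a disulphide isomerase of the endoplasmic reticulum, went from 10070 ± 108.4 to 4770 ± 596.2, the chaperone gene Hsp90b1 from 32520 ± 1809 to 16800 ± 2076 and Creld2 was 2.10-fold lower. That list passed camera without control replicate 1 (0.0321), without knockout replicate 2 (0.0328) or 3 (0.0359), and at a mean value of at least 50 (0.0176), and fry called it lower (0.0259). Of 25 inflammation and NF-kB genes 4 rose and 6 fell, or 4 and 7 adjusted over the list alone (camera adjusted p = 0.279; fry called it lower, adjusted p = 0.00958), and the activation marker Cd69 was 3.34-fold, Ccrl2 3.64-fold and the chemokine gene Ccl6 2.87-fold lower.

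Camera called neither of the cell cycle lists, whose medians turned to 0.04 (replication) and 0.11 (G2/M) after GC and length correction. Of 52 replication genes 1 rose and 9 fell (1 and 4 adjusted over the list alone; median -0.11, camera adjusted p = 0.297), and of 55 G2/M genes 2 rose and 6 fell (1 and 4 adjusted over the list alone; median -0.10, camera adjusted p = 0.235). Cdc6, which loads the replicative helicase, fell from 4250 ± 339.7 to 2517 ± 230.7, Ccne2 (cyclin E2) was 1.79-fold, Hells 1.64-fold, Top2a 1.54-fold and Cdc25b 1.82-fold lower. Cdc20, an activator of the anaphase-promoting complex, rose 1.37-fold (limma adjusted p = 0.0186), a call lost without control replicate 2 (0.101) or 3 (0.0608) and without knockout replicate 2 (0.0571). Of 32 p53 and apoptosis genes 9 rose and 6 fell (10 and 7 adjusted over the list alone; camera adjusted p = 0.398), with Perp higher and the sestrin gene Sesn1 lower (1348 ± 157.9 to 358.3 ± 34.62). Of 34 cytokine and RAS-MAPK genes 7 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.465), with the ERK phosphatase gene Dusp6 1.94-fold lower (limma adjusted p = 0.0104, but 0.0637 without control replicate 3). Of 8 sex-linked genes 6 were tested and 0 passed, and Eif2s3y was at 2124 ± 1909 and 3793 ± 3559.

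Camera called the histone, ribosomal protein and oxidative phosphorylation lists higher in the libraries labelled knockout, with most members of each not called. Of 29 histone genes 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median log2 fold change of 0.70 (camera adjusted p = 0.000607; adjusted p = 0.655 with an estimated correlation, and 0.0852 in fry); the median was 0.45 without knockout replicate 2. The linker histone gene Hist1h1c rose from 346.1 ± 4.118 to 924.7 ± 213.5 and Hist1h2be 2.38-fold. Hist1h1b rose 1.65-fold, a call lost without control replicate 2 (0.0686) or knockout replicate 2 (0.052). Of 73 ribosomal protein genes 15 rose and 3 fell (14 and 3 adjusted over the list alone; median 0.28, camera adjusted p = 0.000304; adjusted p = 0.655 with an estimated correlation, and 0.123 in fry), although Rpl15 was 1.66-fold lower. Rps2 was 1.52-fold lower (limma adjusted p = 0.0097, but 0.0502 without control replicate 3) and Rps21 1.79-fold higher (0.0106, but 0.0553 without control replicate 2). Histone and ribosomal protein genes have near-identical copies and pseudogenes, so their counts are uncertain. Of 58 oxidative phosphorylation genes 5 rose and 3 fell (1 and 1 adjusted over the list alone; median 0.18, camera adjusted p = 0.0117; adjusted p = 0.765 with an estimated correlation, and 0.316 in fry). Ndufv1 of complex I rose 1.59-fold and Sdhb of complex II fell by 0.58 on the log2 scale. Ndufa1, also of complex I, went from 678.3 ± 118.2 to 1012 ± 109.6 (limma adjusted p = 0.0216), a call lost without control replicate 2 (0.107) or 3 (0.063) and without knockout replicate 2 (0.0765). This list's call was lost without control replicate 2 (0.15) or knockout replicate 2 (0.126), in edgeR (0.0506) and after GC and length correction (0.0605).

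Metabolic lists held genes that moved in opposite directions. Of 30 glycolysis and hypoxia genes 9 rose and 3 fell (11 and 4 adjusted over the list alone; median 0.31, camera adjusted p = 0.0907). The prolyl hydroxylase gene Egln3 rose 1.89-fold, while P4ha1, a collagen prolyl hydroxylase, went from 1108 ± 55.48 to 211.6 ± 25.18 and hexokinase 2 (Hk2) was 1.86-fold lower. The list passed camera without knockout replicate 1 (0.0135). Of 24 cholesterol genes 3 rose and 8 fell, or 4 and 8 adjusted over the list alone (median -0.09, mean 0.03, camera adjusted p = 0.648, downwards). Mvd of the mevalonate pathway was 5.19-fold lower. Of 38 ribosome biogenesis and MYC target genes 2 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.489), with the nucleolar gene Pes1 1.48-fold higher. Ldha, lactate dehydrogenase A, was 1.34-fold higher (adjusted p = 0.0153), a call lost without each control replicate in turn (0.0829, 0.083 and 0.0843), and Utp20 was at 472.2 ± 55.04 and 332.9 ± 29.12 (0.0537, but 0.0471 without knockout replicate 3). Of 15 mitochondrially encoded genes 1 rose and 1 fell, also adjusted over the list alone (median -0.02, camera adjusted p = 0.908, upwards). The calls of mt-Nd4, at 30750 ± 428.8 and 21040 ± 5567, and mt-Co2, at 14350 ± 171.2 and 19250 ± 2658, were lost without any 1 control replicate (adjusted p of 0.0665 to 0.0908 and of 0.0936 to 0.101). That of mt-Nd4 was also lost without knockout replicate 2 (0.0588). mt-Nd6, at 3097 ± 442.6 and 4904 ± 1605 (0.0529), passed in edgeR on the recovered reads (0.037). Of the bivalent developmental genes 1 of 63 was tested, the eye and neural factor gene Pax6 at 193.2 ± 22.29 and 138.7 ± 35.3 (limma adjusted p = 0.174), and 0 of 10 HOXB genes reached the mean value of 10.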

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

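All tests of Bap1 and of the lymphoid and myeloid genes below, the restriction of the heat-shock test to 15 genes and its run on male libraries were chosen only after the results they concern had been seen. The share of reads that did not align was flagged in knockout replicate 3, as a signal in data outside the gene counts: it was 11.62%, against 7.93 ± 0.73% in the control libraries (SD, n = 3).

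Bap1 was higher in the libraries labelled knockout, against what the labels lead to. An exchange of labels between a control and a knockout library was argued against, since 0 libraries correlated better with the other group than with their own. Library scaling was argued against too, since the lowest unscaled Bap1 read count of a knockout-labelled library was 1.66 times the highest of a control library. Reads from Bap1 exons outside the deleted part could account for the log2 fold change of 1.39, which stays open because counts per exon were not used here. An exchange of all labels between the groups, in the labels or in the deposited columns, also stays open and was not tested, and it would turn every direction given in this text.

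Lymphoid, dendritic and monocyte lists were lower in the libraries labelled knockout. Fewer cells of every other type in those sorts would lower erythroid genes too. Of 27 erythroid genes tested, 6 rose and 4 fell (median log2 fold change 0.33). The erythroid median lay 3.24 above that of B lymphoid genes (permutation p = 1e-05 over list members, the smallest that 100000 permutations can give). That p treats genes that move together as independent, and both medians had been seen, so it carries no weight. The erythroid values argue only against a loss that takes in erythroid cells. A loss of some types stays open, and of 26 megakaryocyte genes 4 rose and 10 fell. Lymphoid cells carried into the control sorts cannot be told apart from a change within GMPs: of Ms4a1, Cd22 and Cd79b, 0 had at most 3 reads in every control library, and they did not fall alike, since Cd79b kept 872 to 1252 reads in the knockout-labelled libraries (1858 to 2043 in control) while Cd22 kept 0. The effect of genotype on the cells that the gate collects, with Cd34 itself 2.91-fold lower, stays open and was not tested.

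Of 18 heat-shock targets 8 were lower and 0 higher in the libraries labelled knockout, where Cirbp and Rbm3 were higher; the list passed limma camera (adjusted p = 0.000228) but not with an estimated correlation (p = 0.147), and Hsp90ab1, Cct2, Fkbp4 and Hspa4 lay within 0.05 of 0 on the log2 scale. The prediction set for a difference in temperature of the mice or of the cells before lysis was met. The 15 heat-shock targets outside the fixed lists had a median log2 fold change of -0.39 with 6 lower. The 18-gene list, seen before it was cut to these, had -0.43. These medians cannot single out temperature, because lower heat-shock genes from any other cause, genotype included, would give the same. Stronger stress of dissociation and sorting in the control libraries cannot be told apart. The AP-1 and EGR median of 0.38 met the bound set in advance against it, but that bound was poor. The 15 members ran from -1.33 to 1.24 with 2 risen and 2 fallen, and all 15 also stand in a fixed list. A limma camera adjusted p under 0.05 was therefore also required, a condition added after the value was seen. It was not met (adjusted p = 0.566). Sex of the mice was argued against: each group held 1 female, and between the male libraries alone the median of the 15 targets was -0.30, at the bound set for it, and -0.38 to -0.22 over the 4 pairs of libraries (with sex as a term it was -0.39, which the balance fixes). An effect of genotype stays open and was not tested.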

How the results depend on the processing

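The alternatives for pseudocount, a mean value of 50, TMM within limma, sex, and GC content with length were chosen only after the results were seen, while edgeR with TMM had been planned as the main test. Of 116 named genes 102 were called, 75 of them in all of 23 alternatives, and 27 lost the call at least once; 0 reversed. Against a minimum 1.5-fold change edgeR called 417 genes higher and 851 lower, a stricter question by construction. After GC and length correction 2710 were higher. Over 13794 genes the log2 fold change correlated weakly with GC content (Spearman 0.227) and with transcript length (-0.14). The cause was not tested. Without 1 replicate, with fewer samples, 1032 to 1791 were higher and 1372 to 2324 lower. Of the lists, 0 were higher and 0 lower in camera with an estimated correlation, and 0 higher and 10 lower in fry, directional, which asks another question. DESeq2 gave 1929 genes higher and 2326 lower. Replicate numbers did not pair the libraries (r of same-numbered residuals -0.061, 0.025 and -0.015); as a block they gave 1550 higher and 2014 lower, and Hat1 did not pass (adjusted p = 0.0616) while mt-Nd6 did (0.0351). In the simulation, with far fewer changed genes than the data, 16.7% of genes changed 1.5-fold were called, a share that may differ here. A gene not called here is not shown to be unchanged.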

Other observations

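The globin and germ-cell genes and the genes silent in a group were chosen only after other results were seen, and the count of splits was planned. Globin genes rose in the libraries labelled knockout: Hbb-bs by 3.03, Hbb-bt by 3.14, Hba-a1 by 1.81 and Hba-a2 by 2.72 on the log2 scale, with reads that near-identical copies make uncertain. The Hba-a1 call was lost without control replicate 2, knockout replicate 2 or knockout replicate 3, and that of Hba-a2 without knockout replicate 2 or 3. At most 3 reads per control library and a value of at least 10 in every knockout-labelled library were found for 36 genes, among them Meiob (0 to 81.39), and the reverse for 82, among them Cyp39a1 (173.2 to 0), Tlr1 (129.1 to 0) and Hoxa5 (19.15 to 0.7613).

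Meiob, Pnldc1, Tsga10ip and Tcp11x2, silent in control libraries, led to the hypothesis of a release of germ-cell genes as a class in the knockout libraries, tested on 15 other germ-cell genes. Of these 4 rose (Tesmin, Rec8, Dmc1 and Stag3) and 2 fell (Tdrkh and Mei4), with a median log2 fold change of 0.02 (exact binomial p = 0.688), so the test did not decide. The Stag3 call was lost in 5 of the fits that leave out a library.

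The 6 libraries allow 10 splits into groups of 3, too few to tell any count from chance. For genes past the threshold, 1 of 10 splits gave as many as the real 3858, and the highest other gave 0. For gene lists 4 of 10 gave at least the real 10, and the highest other gave 15. For genes silent in a group 1 of 10 gave as many as the real 118, and the highest other gave 5. The other splits gave 5 to 15 lists, but each keeps a part of the real difference between the groups, so these are not counts without any change. The same holds for the 0 called and 5 silent genes. Each other split mixes libraries of both groups, so the real difference adds to the spread within its groups. Low counts of such genes were therefore largely fixed in advance.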
